A study of Mus musculus with 12 samples.

How the data were processed

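The study measured total RNA of peritoneal lavage cells by sequencing on a Solexa platform, per the labels' protocols, in 12 libraries from wild-type and lactoferrin knockout C57BL/6J mice injected with PBS or LPS. The RNA was taken up with a kit that also keeps small RNA, per the labels' protocols. The titles of the knockout libraries speak of wild-type mice, while their codes and the characteristics say lactoferrin knockout, and the latter were used. Groups and replicate numbers were taken from these labels, with 3 libraries in each of 4 groups.

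The authors deposited 1 table per library with a gene symbol and a value. The unit is not stated there. The deposited values were taken as FPKM, fragment counts scaled by transcript length and library total, because they are not whole, sum to between 343874 and 388129 in a library and reach down to vanishingly small estimates, and because Cufflinks is among the tools named. TopHat, Cufflinks, HTSeq, DESeq and the genome build GRCm38 are named in the submitters' processing notes, with no version, role or order. The annotation, the filters and the use of strand are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies cannot be separated further than the authors' values do. Of 21878 rows in each table, 27 had a symbol that spreadsheet software had turned into a date, and these were left out, which left 21851. Of these, 5228 were at 0 in every library. Mitochondrially encoded transcripts, immunoglobulin constant regions, T cell receptor constant regions, Xist and the Mx genes were not analysed here.

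An FPKM value does not carry the number of reads behind it, so counting intervals cannot be given. The relative depth was estimated from genes below 0.2 FPKM in a pair of libraries, where the value of 1 read sets the smallest steps and the most common ratio of a pair gives the ratio of their depths. It lay between 0.928 and 0.992 of wild-type PBS replicate 1 for the other libraries, so depth differed little between the groups. No more than 18.3% of such pairs lay within 2% of the most common ratio, so whole reads were not recovered. Genes of low level rest on few reads and their fold changes are shrunk by the added 1 FPKM.

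The design fixed before the data were examined assumed read counts and a count model. Since the files hold FPKM, which is not suited to a count model, the test was instead limma on log2(FPKM + 1), with the same groups, contrasts and threshold. Genes with a mean of at least 1 FPKM over the 12 libraries were tested, 9841 of 21851 or 45.0%. A linear model with a mean for each of the 4 groups was fitted to all 12 libraries, which thus share an estimate of the spread with 8 residual degrees of freedom. The variances were shrunk towards a trend with robust hyperparameters. The contrasts were LPS against PBS within each genotype, knockout against wild type within each treatment, and the interaction, the LPS response of the knockout less that of wild type. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. The median SE of a log2 fold change was 0.141, and 0.199 for the interaction.

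There were 37 gene lists of cell types and pathways fixed before the data were examined, of which 33 had at least 3 tested members. Eosinophil, mesothelial, platelet and mitochondrially encoded lists had fewer. The lists were tested with camera at its preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, and the p-values were adjusted over the 33 lists. Camera compares a list with the other genes, while fry asks whether its genes move, on balance, in 1 direction. For each list the genes were also counted after adjustment over the list alone. The genes named were Ltf, then the 8 highest and the 8 lowest called genes of a contrast with at least 5 FPKM and, for contrasts of a pair of groups, no overlap of the groups, leaving out predicted genes and receptor segments. From each list up to 4 called members with the largest change were named, or, with none called, up to 2 with the highest level, given as values. That rule was written for CPM and was applied to FPKM.

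Positions were taken from the GENCODE annotation of GRCm38, in which 9533 of the 9841 tested genes (96.9%) had a position. Exact tests enumerated every relabelling. The statistics ran in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and the figures in Python 3.11.15 with matplotlib 3.10.9.

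The test was run on simulated data with the real genes' means and 200 changed genes, 100 at each of the sizes 1 and 2 on the log2 scale. The spreads were drawn at random from the distribution that limma had fitted to the real genes. At size 1 it recovered 80 of 100 genes for LPS in wild type, 77 for LPS in the knockout, 87 for the knockout under PBS, 86 for the knockout under LPS and 71 for the interaction. At size 2 it recovered 98, 97, 96, 99 and 95 of 100, with 6, 3, 3, 17 and 4 false calls over both sizes in 9841 genes. A list moved as a whole was called in each contrast, beside 0, 1, 1, 1 and 0 lists that had not been moved. The simulation held no correlation between genes and no outlying library, and its spreads followed the model that limma assumes. Its recovery and false calls are thus those of a favourable case.

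Alternatives fixed before the data were examined were scaling by median of ratios and by the upper quartile, no filter, a stricter filter of at least 1 FPKM in at least 6 libraries, a pseudocount of 0.1, a fit of only the groups of a contrast, the replicate number as a block, the other tests of lists, windows of 5 Mb and 20 Mb around Ltf, and each library left out in turn. Added after the data were seen were limma without robust shrinkage, all results without the 2 libraries richest in erythroid RNA, and an exact permutation of list means for the interaction. No pair of libraries shared more than 0.00873% of identical values, so each was counted as its own sample. Y-linked genes were expressed in every library, with Ddx3y between 13.9 and 19.9 FPKM.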

Results

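RNA was sequenced from cells of the peritoneal lavage of C57BL/6J mice that were wild type or lacked lactoferrin, the iron-binding protein of neutrophil granules and secretions that Ltf encodes. The mice had received an intraperitoneal injection of PBS or of LPS, the bacterial lipopolysaccharide that is sensed through Tlr4. The 12 libraries formed 4 groups of 3, and the series asks how the loss of lactoferrin alters gene expression in acute LPS inflammation. The dose and the time between injection and lavage are not given in the sources used here. Each library listed 21878 genes in FPKM, with totals between 343874 and 388129 FPKM and between 13921 and 14574 genes above 0. Read totals are not given, but the most common ratio of values below 0.2 FPKM put the depth of the other 11 libraries at 0.928 to 0.992 of that of wild-type PBS replicate 1, with 9.29% to 18.3% of the gene pairs within 2% of that ratio. The first principal component held 76.6% of the variance and separated the LPS from the PBS libraries. Wild-type PBS replicate 3 stood apart from its group, with Spearman correlations of 0.949 and 0.934 to the other 2 libraries, while the other pairs within groups had at least 0.973. The labels name no sorting of the lavage, so a level is a mean over macrophages, neutrophils, lymphocytes and whatever other cells it held. The labels number the libraries within each group without saying that each came from a separate mouse, so p-values measure the spread between libraries.

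Ltf was measured first, as a check of the labels. Its level was 1.43 ± 0.402 FPKM (SD, n = 3) in wild type under PBS and 0.218 ± 0.0376 FPKM (SD, n = 3) in the knockout under PBS. Under LPS it was 0.593 ± 0.639 FPKM (SD, n = 3) in wild type, where the libraries were at 0.176, 1.33 and 0.275 FPKM, and 0.0899 ± 0.024 FPKM (SD, n = 3) in the knockout. Every knockout library was below every wild-type library under PBS, as it was under LPS, where wild-type replicate 1 at 0.176 FPKM lay close to the highest knockout library at 0.117 FPKM. Over both treatments the knockout was lower by a difference of -0.73 on the log2(FPKM + 1) scale (two-sided exact permutation of genotype within treatment, p = 0.005, the smallest that 400 permutations can give). Within a treatment 3 libraries against 3 cannot go below p = 0.1, and that value was reached under PBS and under LPS (exact permutation). Ltf lies on chromosome 9 of GRCm38 at 111019271 to 111042767, on the plus strand. Its mean over all libraries, 0.582 FPKM, was under the minimum of 1 FPKM, so it was not among the 9841 genes tested.

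**Figure D1:**
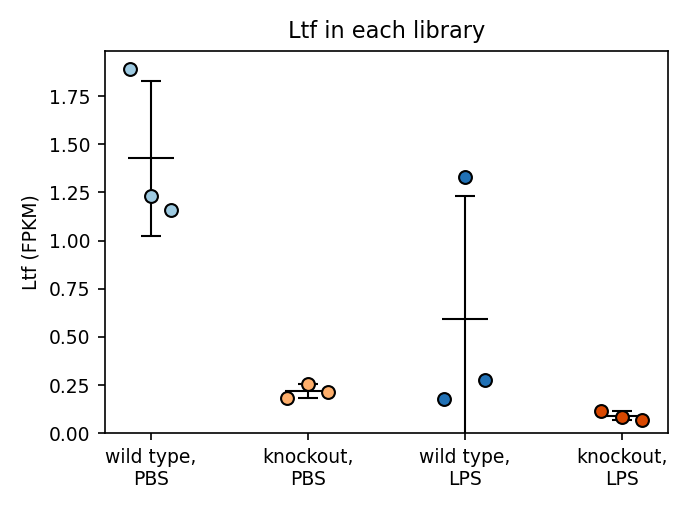
Ltf in FPKM (vertical axis) in each of the 12 libraries, grouped by genotype and treatment (horizontal axis). Points are libraries, horizontal lines are group means and bars are 1 SD over 3 libraries; the knockout means are 0.218 FPKM under PBS and 0.0899 FPKM under LPS, and the wild-type means 1.43 and 0.593 FPKM.

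The response of wild-type cells to LPS was led by inflammatory mediators. Nos2, the inducible nitric oxide synthase, rose from 2.17 ± 0.826 to 107 ± 15.7 FPKM (SD, n = 3), and Cxcl10, an interferon-induced chemokine, from 36.8 ± 10.5 to 1235 ± 111 FPKM (SD, n = 3). Csf3, which encodes the granulocyte colony-stimulating factor, rose from 0.601 ± 0.37 to 42.9 ± 9.69 FPKM, and Il6 from 36.7 ± 24.2 to 239 ± 123 FPKM (SD, n = 3). In the opposite direction, Cxcr2, the neutrophil receptor for Cxcl1 and related chemokines, fell from 67.7 ± 30 to 0.793 ± 0.275 FPKM (SD, n = 3). Ccr2, the chemokine receptor of inflammatory monocytes, fell from 56.5 ± 9.57 to 1.99 ± 0.338 FPKM, and S100a8, a calprotectin subunit abundant in neutrophils, from 1203 ± 286 to 90.0 ± 34 FPKM (SD, n = 3).

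In total 6123 of the 9841 genes tested changed with LPS in wild type at an adjusted p under 0.05 by limma, 2443 higher and 3680 lower. The change passed 1 on the log2 scale in 690 of the higher and 1356 of the lower genes. Fold changes here and below are on the log2(FPKM + 1) scale, which understates the change of low genes. The highest among genes of at least 5 FPKM whose groups did not overlap were those of Ptx3 (5.15 ± 0.55), Nos2 (5.11 ± 0.31), Cxcl10 (5.07 ± 0.45), Csf3 (4.78 ± 0.22), Cxcl1 (3.91 ± 0.46), Fam26f (3.86 ± 0.33), Iigp1 (3.72 ± 0.51) and Slamf1 (3.60 ± 0.15), each with its SE from limma. The lowest were those of Cxcr2 (-5.15 ± 0.55), Cd300lb (-5.06 ± 0.18), Clec7a (-4.87 ± 0.30), Clec4n (-4.78 ± 0.30), Ccr2 (-4.26 ± 0.17), Retnlg (-4.19 ± 0.53), G0s2 (-4.09 ± 0.39) and Cass4 (-4.09 ± 0.29). Clec7a and Clec4n encode receptors for fungal glucans and mannans. The median of all tested genes was -0.11 on the log2 scale, and scaling by median of ratios moved it to -0.006 and the split of calls to 3054 higher and 3124 lower, so small falls are to be read against that median.

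Among the gene lists, 32 of 36 type I interferon response genes rose with LPS in wild type, and 33 did when adjusted over the list alone, with a median log2 fold change of 1.33. Isg15, a ubiquitin-like modifier, went from 91.2 ± 29.9 to 488 ± 30.7 FPKM (SD, n = 3), Oasl1 rose by 2.69 ± 0.33 and Ifi44 by 2.67 ± 0.18 (SE). Of 26 genes of the interferon gamma response and the guanylate-binding protein family, 24 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 1.73, led after Nos2 by Iigp1, Gbp6 (2.87 ± 0.36) and Tgtp1 (2.80 ± 0.33). Camera at its preset correlation gave adjusted p = 4.41e-11 and adjusted p = 1.54e-08 for these lists, against adjusted p = 0.863 for each with an estimated correlation. Inflammatory cytokine and NF-kB target genes rose in 22 and fell in 3 of 33 (median 0.81), among them Edn1 (3.57 ± 0.24) and Il1a (3.35 ± 0.33), while Il1b was lower (-0.84 ± 0.32). Chemokine genes rose in 13 and fell in 4 of 22 (median 1.37), with Ccl3 at 2.77 ± 0.29 and Ccl5 at 2.63 ± 0.36. Negative regulators of Toll-like receptor signalling rose in 14 and fell in 2 of 22 (median 1.10), with Tnfaip3 (3.22 ± 0.28), Il10 (2.30 ± 0.38) and Cd274 (2.16 ± 0.22) highest. The counts of these 3 lists were the same when adjusted over the list alone, and camera gave adjusted p = 4.27e-06, adjusted p = 0.00644 and adjusted p = 0.00214, against adjusted p = 0.863 for each with an estimated correlation.

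Genes of several leukocyte types fell in wild type under LPS. Of 20 mature neutrophil genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -2.35, among them Cxcr2, Retnlg, Asprv1 (-4.01 ± 0.40) and S100a9 (-3.91 ± 0.53), the partner of S100a8. Of 13 monocyte genes, 11 fell and 1 rose, also adjusted over the list alone, with a median of -1.36, among them Chil3 (-3.64 ± 0.65) and Ly6c2 (-2.23 ± 0.33). Of 12 genes of MHC class II presentation, 10 fell and none rose, also adjusted over the list alone, with a median of -1.56, among them H2-Ob (-2.40 ± 0.31) and H2-DMb1 (-1.98 ± 0.46). T cell genes fell in 10 of 11, also adjusted over the list alone, with a median of -0.76, led by Thy1 (-1.53 ± 0.26) and Cd3g (-1.44 ± 0.21). These 4 lists had adjusted p = 0.000566, adjusted p = 0.00825, adjusted p = 0.0157 and adjusted p = 0.0283 by camera, and adjusted p = 0.863 for each with an estimated correlation. The T cell call was lost without wild-type PBS replicate 2 (adjusted p = 0.0834 by camera). B cell genes fell in 10 and rose in 1 of 19 (median -0.58) and large peritoneal macrophage genes fell in 9 and rose in 2 of 18 (median -1.25), both also adjusted over the list alone, but camera did not call these lists (adjusted p = 0.125 and adjusted p = 0.156). Natural killer genes went both ways, 2 up and 4 down of 10, also adjusted over the list alone (median -0.20), with Tbx21 (1.95 ± 0.28) and Gzmb (1.51 ± 0.39) higher. Of 11 mast cell genes 2 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.27), with Fcer1a at 1.68 ± 0.50. Camera did not call these lists either (adjusted p = 0.814 and adjusted p = 0.265). In the cell cycle list 9 genes rose and 1 fell of 26, against 8 and 0 adjusted over the list alone, and those that rose most, Mcm5 (2.05 ± 0.23), Mcm2 (2.03 ± 0.24) and Mcm3 (2.0 ± 0.21), encode subunits of the replicative helicase. Its median was 0.11, and its camera adjusted p = 0.0243 became adjusted p = 0.863 with an estimated correlation and adjusted p = 0.113 without wild-type PBS replicate 1. The camera calls were 10 lists of 33 in all, 6 up and 4 down, and 22 lists, 6 up and 16 down, were called by fry, which tests each list alone. Fry tests against 0 and was run without rescaling, while the median of all tested genes was -0.11. Its downward calls are to be read against that median. They included the LPS sensing list at a median of -0.05 (adjusted p = 0.00419 by fry).

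In the knockout, LPS raised the same kinds of mediators. Nos2 rose from 1.90 ± 1 to 109 ± 40.3 FPKM, Csf3 from 0.474 ± 0.412 to 53.1 ± 7.82 FPKM and Cxcl1 from 46.9 ± 22 to 819 ± 165 FPKM (SD, n = 3). Tnf rose from 21.8 ± 10.4 to 70.8 ± 29.1 FPKM and Il1b from 65.3 ± 23.1 to 172 ± 47.4 FPKM (SD, n = 3). Ccr2 fell from 50.6 ± 6.97 to 2.15 ± 0.65 FPKM. S100a8 was at 762 ± 460 FPKM under PBS and 801 ± 462 FPKM under LPS (SD, n = 3), a log2 difference of 0.02 ± 0.51 (SE) that did not pass the test.

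Of the 9841 genes, 5235 changed with LPS in the knockout by limma, 1958 higher and 3277 lower. The highest by the same rule were Nos2 (5.24 ± 0.31), Csf3 (5.22 ± 0.22), Cxcl10 (4.72 ± 0.45), Cxcl3 (4.37 ± 0.39), Cxcl1 (4.20 ± 0.46), Mt2 (4.18 ± 0.43), Ptx3 (4.09 ± 0.55) and Ctla2b (4.0 ± 0.31). The lowest were Ccr2 (-4.05 ± 0.17), Tmem37 (-4.03 ± 0.30), Slc9a3r2 (-3.94 ± 0.16), Cd300lb (-3.83 ± 0.18), Ccnd1 (-3.74 ± 0.21), AI467606 (-3.64 ± 0.18), Rasa3 (-3.63 ± 0.22) and S1pr1 (-3.60 ± 0.25). The median of all tested genes was -0.12, and median-of-ratios scaling moved it to -0.003 and the split to 2659 higher and 2600 lower.

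Type I interferon response genes rose in 30 of 36 in the knockout (median 1.05), and interferon gamma response genes rose in 24 and fell in 1 of 26 (median 1.37). Cytokine and NF-kB target genes rose in 24 and fell in 1 of 33 (median 1.29), chemokine genes rose in 14 and fell in 3 of 22 (median 1.68), and negative regulators rose in 16 and fell in 3 of 22 (median 1.32). Adjusted over the list alone these counts were 30 higher, 24 higher with 1 lower, 24 higher with 2 lower, 14 higher with 3 lower and 17 higher with 3 lower. Camera called all 5 lists, with adjusted p = 1.28e-11, adjusted p = 3.3e-10, adjusted p = 5.22e-11, adjusted p = 1.79e-05 and adjusted p = 5.93e-06. With an estimated correlation the cytokine and chemokine lists had adjusted p = 0.753 and the others adjusted p = 0.863. Glycolysis and hypoxia genes rose in 13 and fell in 2 of 24 (14 and 2 adjusted over the list alone, median 0.60), among them Pfkfb3 (3.11 ± 0.28), an activator of glycolysis, and Hk2 (1.78 ± 0.19), a hexokinase. The unfolded protein response list rose in 4 and fell in 1 of 19 (4 and 0 adjusted over the list alone, median 0.35), and 1 of 32 ribosomal protein genes rose (0 adjusted over the list alone, median 0.16). By camera these lists had adjusted p = 0.00161, adjusted p = 0.0177 and adjusted p = 0.0177, and adjusted p = 0.863 for each with an estimated correlation. The ribosomal call was lost without knockout PBS replicate 1 or knockout LPS replicate 2, and the unfolded protein response call without knockout LPS replicate 3. Camera thus called 8 lists, all upward with these settings, and fry called 16, 7 up and 9 down. Among the downward calls of fry was the Y-linked list, a check of the animals' sex (median -0.30, adjusted p = 0.00145 by fry). Fry tests against 0 and was run without rescaling, while the median of all tested genes was -0.12. Camera calls were 8 up and 3 down with median-of-ratios and with upper-quartile scaling, 8 up and 4 down without the filter and 9 up and 3 down without the 2 libraries richest in erythroid RNA.

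Mature neutrophil genes fell in 4 and rose in 2 of 20 in the knockout under LPS (4 and 1 adjusted over the list alone), with a median of -0.47 and no call by camera (adjusted p = 0.593). Those that fell most were Cxcr2 (-2.72 ± 0.55), Mmp9 (-2.42 ± 0.32) and Padi4 (-2.22 ± 0.34), while Hcar2 rose by 1.81 ± 0.23 (SE). In the neutrophil granule list Ngp rose by 3.82 ± 0.46 and Lcn2, an iron-siderophore trap, by 2.68 ± 0.45, while Prtn3 and Cebpe fell (-2.14 ± 0.51 and -1.91 ± 0.22). T cell genes fell in 2 of 11 over all genes and in none adjusted over the list alone (median -0.32), and B cell genes fell in 12 and rose in 1 of 19 (12 and 2 adjusted over the list alone, median -0.98). Large peritoneal macrophage genes fell in 13 and rose in 1 of 18, also adjusted over the list alone (median -1.11).

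The LPS responses of the 2 genotypes were close across genes, with Pearson r = 0.912 and Spearman rho = 0.908 over 9841 genes, which are not independent replicates. Of the calls, 1750 genes were higher in both genotypes, where independent lists of those sizes would share 486, and 2870 were lower in both, where they would share 1225. Only 8 genes were called in opposite directions. The comparisons have no library in common.

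**Figure D2:**
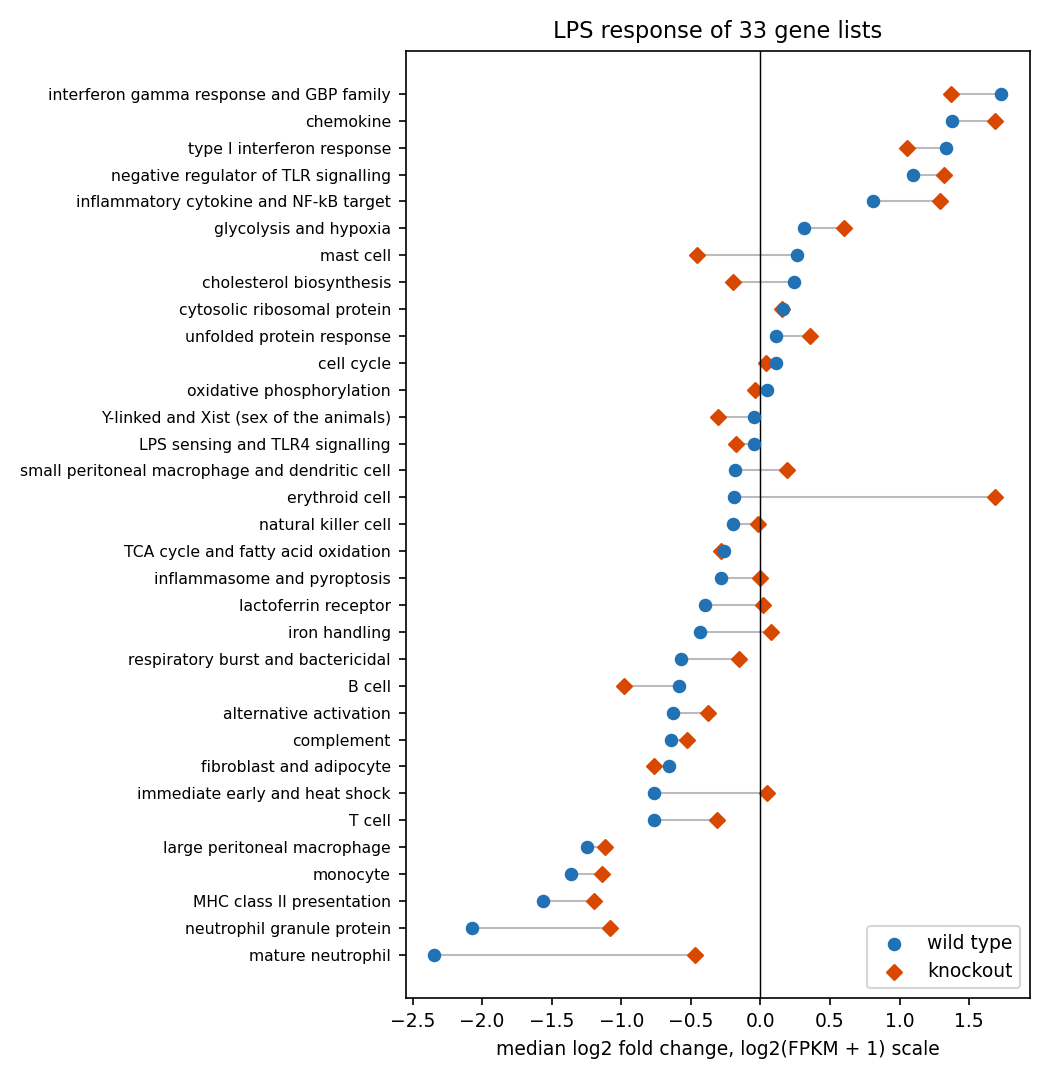
Median log2 fold change of 33 gene lists, LPS against PBS on the log2(FPKM + 1) scale (horizontal axis), with each list on its own line, in wild type (circles) and knockout (diamonds). The mature neutrophil list lies at -2.35 in wild type and at -0.47 in the knockout, and the interferon gamma list at 1.73 and 1.37; the erythroid list lies at 1.69 in the knockout, 1 of whose LPS libraries held 1886 FPKM of erythroid RNA.

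Without LPS, the knockout differed from wild type in few genes, and 2 of them, Egr1 and Egr2, are of the immediate early list, genes that answer stimuli within minutes. Egr1, a zinc-finger transcription factor, fell from 25.5 ± 2.36 to 13 ± 2.23 FPKM, and Egr2 from 5.49 ± 0.722 to 1.81 ± 0.479 FPKM (SD, n = 3). Csrnp1 fell from 14.8 ± 1.26 to 6.90 ± 0.989 FPKM and Pdcd4, an inhibitor of translation, from 42.4 ± 6.81 to 17.1 ± 1.59 FPKM (SD, n = 3). Dagla, an enzyme of endocannabinoid synthesis, rose from 3.43 ± 0.697 to 7.38 ± 1.41 FPKM.

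By limma 11 of 9841 genes passed, 2 higher and 9 lower, and 897 had an unadjusted p under 0.05, where 492 would be expected. The rule fixed before the data were examined named Pdcd4 (-1.25 ± 0.19), Cited2 (-1.16 ± 0.17), Csrnp1 (-1.01 ± 0.12), Egr1 (-0.93 ± 0.14) and Dagla (0.92 ± 0.14), and, as list members, Egr2 (-1.21 ± 0.13) and Klrd1 (-0.93 ± 0.15), which encodes a natural killer receptor subunit. Among the others, named after their values were seen, were Arntl (0.96 ± 0.13), a core transcription factor of the circadian clock, Ch25h (-1.06 ± 0.15) and Hbegf (-0.96 ± 0.13), a ligand of the epidermal growth factor receptor. The smallest adjusted p by limma was 0.0111, for Csrnp1 and Egr2. The count was 0 when only the 6 PBS libraries were fitted, 0 without the libraries richest in erythroid RNA, and between 0 and 39 with 1 library left out.

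T cell genes were lower in the knockout under PBS in 11 of 11 when adjusted over the list alone and in 0 over all genes, with a median of -0.79. Thy1 was at 10.4 ± 3.77 and 5.37 ± 0.276 FPKM and Cd3g at 8.07 ± 1.56 and 3.06 ± 1.26 FPKM in wild type and knockout (SD, n = 3). Natural killer genes had a median of -0.69, with 1 of 10 lower over all genes and 5 adjusted over the list alone. Camera gave adjusted p = 6.15e-13 and adjusted p = 4.34e-07 for these lists, against adjusted p = 0.465 and adjusted p = 0.556 with an estimated correlation. None of 12 MHC class II genes passed, over all genes or adjusted over the list alone, and all 12 were below 0 (median -0.61), with Cd74 at 2532 ± 84.1 and 1674 ± 324 FPKM (SD, n = 3). Cholesterol biosynthesis genes were above 0 in 20 of 22 (median 0.48), with 7 higher adjusted over the list alone and 0 over all genes, among them Idi1 at 4.33 ± 1.91 and 8.62 ± 1.39 FPKM (SD, n = 3). The MHC class II list had adjusted p = 0.000124 by camera and adjusted p = 0.684 with an estimated correlation, and the cholesterol list adjusted p = 1.75e-10 and, with an estimated correlation, adjusted p = 0.556. Type I interferon genes were above 0 in 34 of 36 (median 0.28), with 0 passing over all genes or adjusted over the list alone, and a camera adjusted p = 4.34e-07 that became adjusted p = 0.754 with an estimated correlation. That camera call was lost without knockout PBS replicate 3, where the type I interferon median was 0.11.

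The immediate early and heat shock list had a median of -0.26, with 2 of 21 lower over all genes and 3 adjusted over the list alone. Chemokine genes had a median of -0.45 with 0 passing over all genes and, adjusted over the list alone, 4 lower and 1 higher; the latter chemokine, Cxcl13, a B cell attractant made by peritoneal macrophages, was at 972 ± 618 and 2945 ± 1285 FPKM in wild type and knockout (SD, n = 3). Camera gave adjusted p = 0.00294 and adjusted p = 0.00493 for these lists, against adjusted p = 0.769 and adjusted p = 0.684 with an estimated correlation. Large peritoneal macrophage genes had a median of 0.12, with 0 passing over all genes and 3 higher adjusted over the list alone, and mast cell genes a median of 0.37 with 0 passing by either adjustment. These had adjusted p = 0.0272 and adjusted p = 0.00493 by camera, and adjusted p = 0.866 and adjusted p = 0.754 with an estimated correlation. Lists called downward with 0 genes passing over all genes were those of small peritoneal macrophages and dendritic cells (median -0.39), the interferon gamma response (median -0.27), cytokines and NF-kB targets (median -0.16) and ribosomal proteins (median -0.14). Adjusted over the list alone they had 0, 1, 3 and 0 lower genes. Their camera adjusted p = 0.0202, adjusted p = 0.00344, adjusted p = 0.0165 and adjusted p = 0.0434 became adjusted p = 0.684, adjusted p = 0.866, adjusted p = 0.866 and adjusted p = 0.972 with an estimated correlation. In all, camera called 13 lists, 4 up and 9 down, and fry called 0. With each library left out in turn, only the T cell, natural killer, MHC class II and cholesterol calls were kept throughout. The large peritoneal macrophage median ran from -0.22, without wild-type PBS replicate 2, to 0.59, without replicate 3. Its call was lost without wild-type PBS replicate 1 or 2 or knockout PBS replicate 2, so its direction rests on single libraries. The ribosomal median ran from -0.27 to -0.014. Its test turned direction without wild-type PBS replicate 3, and its call was lost there and without wild-type PBS replicate 1, wild-type LPS replicate 2 or 3, knockout PBS replicate 1 or knockout LPS replicate 1. It was also lost without the 2 libraries richest in erythroid RNA. The immediate early, chemokine and cytokine calls were lost without wild-type PBS replicate 1 or 2. The mast cell call was lost without wild-type PBS replicate 2 or knockout PBS replicate 2. The small peritoneal macrophage and dendritic cell call was lost without wild-type PBS replicate 1 or 3 or knockout PBS replicate 3. The interferon gamma call was lost without replicate 1 or 2 of either PBS group.

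Under LPS no single gene passed between the genotypes. All 20 mature neutrophil genes were above 0 in the knockout, but the camera call of their list was lost with an estimated correlation (adjusted p = 0.15) and fry did not call it (adjusted p = 0.194). S100a8 was at 90.0 ± 34 FPKM in wild type and 801 ± 462 FPKM in the knockout (SD, n = 3), a log2 difference of 3.02 ± 0.51 (SE) with adjusted p = 0.145 by limma. S100a9 differed by 3.25 ± 0.53 with adjusted p = 0.124, and Retnlg was at 9.23 ± 2.55 and 85.5 ± 52.7 FPKM (SD, n = 3). Each knockout LPS library lay above each wild-type LPS library in S100a8, with knockout levels of 1241, 320 and 843 FPKM against 51.4, 103 and 116 FPKM.

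The count by limma was 0 of 9841 genes, with 744 at an unadjusted p under 0.05, where 492 would be expected, and the smallest adjusted p = 0.124. It was 3 when only the 6 LPS libraries were fitted, 2 without the filter on low values and 29 without knockout LPS replicate 2, which had the lowest neutrophil levels of its group. In the mature neutrophil list all 20 genes were above 0, with a median of 1.09, and 14 were higher adjusted over the list alone. Of 9 neutrophil granule genes all were above 0 (median 0.53), with 3 higher adjusted over the list alone, and of 13 monocyte genes 11 were (median 0.39), with 1 higher adjusted over the list alone. Camera gave adjusted p = 5.18e-24, adjusted p = 3.84e-06 and adjusted p = 1.65e-05, against adjusted p = 0.15, adjusted p = 0.15 and adjusted p = 0.26 with an estimated correlation. Erythroid RNA was high in 1 library of each genotype under LPS, with 2226 FPKM summed over hemoglobin and other erythroid genes in wild-type replicate 2 and 1886 FPKM in knockout replicate 1, which also had the highest S100a8 of the LPS libraries. Without these 2 libraries the neutrophil median was 1.01 (camera adjusted p = 8.79e-13, and adjusted p = 0.595 with an estimated correlation).

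**Figure D3:**
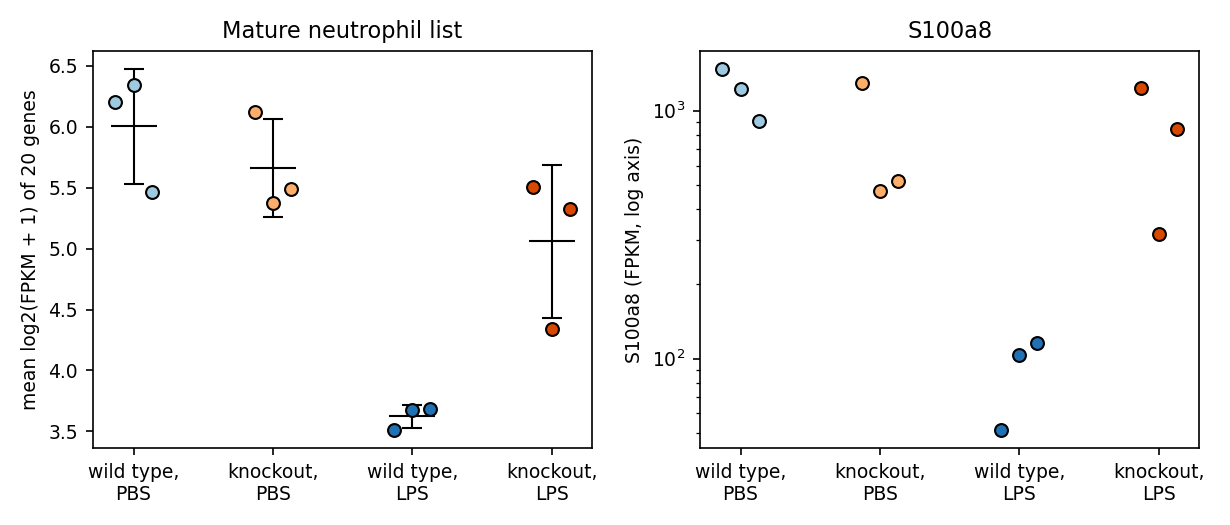
Mean log2(FPKM + 1) of the 20 mature neutrophil genes (left, vertical axis; lines are means and bars 1 SD over 3 libraries) and S100a8 in FPKM on a log axis (right) in each library, by genotype and treatment (horizontal axes). The wild-type LPS libraries lie below all others on the left, between 3.51 and 3.68, and the knockout LPS libraries between 4.34 and 5.51.

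Immediate early and heat shock genes were above 0 in the knockout under LPS in 18 of 21 (median 0.41), with 4 higher adjusted over the list alone, and glycolysis genes in 21 of 24 (median 0.21), with 1 higher. Camera gave adjusted p = 1.01e-09 and adjusted p = 4.03e-08, against adjusted p = 0.26 and adjusted p = 0.327 with an estimated correlation. All 26 interferon gamma response genes were below 0 (median -0.39), with 0 passing by either adjustment. Gbp2, a guanylate-binding protein, was at 269 ± 33 FPKM in wild type and 183 ± 35.5 FPKM in the knockout (SD, n = 3), and the list had adjusted p = 1.38e-05 by camera and adjusted p = 0.512 with an estimated correlation. T cell and cell cycle genes were called downward (medians -0.23 and -0.18, adjusted p = 0.0473 and adjusted p = 0.031 by camera), with 0 genes passing by either adjustment and adjusted p = 0.672 and adjusted p = 0.512 with an estimated correlation. Among the cytokines, Il1rn, the interleukin 1 receptor antagonist, was at 296 ± 31.5 and 572 ± 146 FPKM in wild type and knockout (SD, n = 3), and Cd14, the LPS co-receptor, at 593 ± 99.1 and 1183 ± 221 FPKM (SD, n = 3). Neither passed by limma (adjusted p = 0.349 and adjusted p = 0.499).

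Camera called 9 further lists upward under LPS, with small medians: chemokine (0.32), iron handling (0.27), respiratory burst (0.18), negative regulators (0.18), inflammasome (0.11), alternative activation (0.11), cholesterol biosynthesis (0.09), cytokine (0.07) and type I interferon (0.07). No gene of these lists passed over all genes. Adjusted over the list alone, 3 negative regulators, 2 respiratory burst genes, 1 iron gene and 1 alternative activation gene were higher and 1 chemokine was lower. Their camera adjusted p lay between 7.15e-05 and 0.0408, and with an estimated correlation between adjusted p = 0.15 and adjusted p = 0.699. Of 33 lists, 17 were called by camera, 14 up and 3 down, and 0 by fry. Without the 2 erythroid-rich libraries camera called 12, 9 up and 3 down, with 10 of them among the 17. The cytokine, type I interferon, negative regulator, iron handling, alternative activation and cell cycle calls were lost there, as was that of the cholesterol list, which turned to a median of -0.076. With 1 library left out the cholesterol median ran from -0.11, without knockout LPS replicate 1, to 0.27. Its call was lost without replicate 1 or 2 of either LPS group, with the direction turned without knockout LPS replicate 1. The negative regulator and alternative activation calls were lost without wild-type LPS replicate 2, the latter at a median of -0.025. The chemokine call was lost without knockout LPS replicate 2, and the inflammasome call without replicate 3 of either LPS group. The cytokine call was lost without wild-type LPS replicate 2 or knockout LPS replicate 2 or 3. The type I interferon call was lost without wild-type LPS replicate 2 or knockout LPS replicate 1 or 2. The T cell call was lost without wild-type PBS replicate 3, wild-type LPS replicate 1 or knockout LPS replicate 3. The cell cycle call was lost without wild-type PBS replicate 3 or replicate 1 or 2 of either LPS group.

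The LPS response differed between the genotypes, tested as an interaction, in 4 genes, among them Egr1 and Egr2 of the immediate early list. Egr1 fell with LPS in wild type, from 25.5 to 9.30 ± 0.587 FPKM, and was at 13 and 15.4 ± 2.77 FPKM in the knockout (SD, n = 3), an interaction of 1.59 ± 0.20 (SE) with adjusted p = 0.0344 by limma. For Hbegf it was 1.39 ± 0.18 (adjusted p = 0.0344), for Egr2 1.33 ± 0.19 (adjusted p = 0.0446) and for Csrnp1 1.15 ± 0.16 (adjusted p = 0.0446), all by limma. Csrnp1 fell with LPS in wild type (-0.47 ± 0.12) and rose in the knockout (0.68 ± 0.12), and Hbegf rose in the knockout (1.17 ± 0.13). Egr2 was lower under LPS in both genotypes, between 0.403 and 0.462 FPKM in wild type and between 0.45 and 0.665 FPKM in the knockout. These levels are near the floor of the scale, so its interaction largely restates the difference under PBS. With a pseudocount of 0.1 the call of Egr2 was lost. Hbegf, at under 5 FPKM and in none of the lists, is named after its values were seen. These were the calls among 9841 genes, all higher, with 946 at an unadjusted p under 0.05 where 492 would be expected. The PBS libraries that set their knockout difference also enter the interaction, so the calls are not independent of those under PBS. The count was 8 and 12 with median-of-ratios and upper-quartile scaling, 0 without the 2 libraries richest in erythroid RNA and between 0 and 49 with 1 library left out. It was 0 with the replicate number as a block and 1 without the filter, Hist1h4f, so none of these 4 genes was called in either setting.

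**Figure D4:**
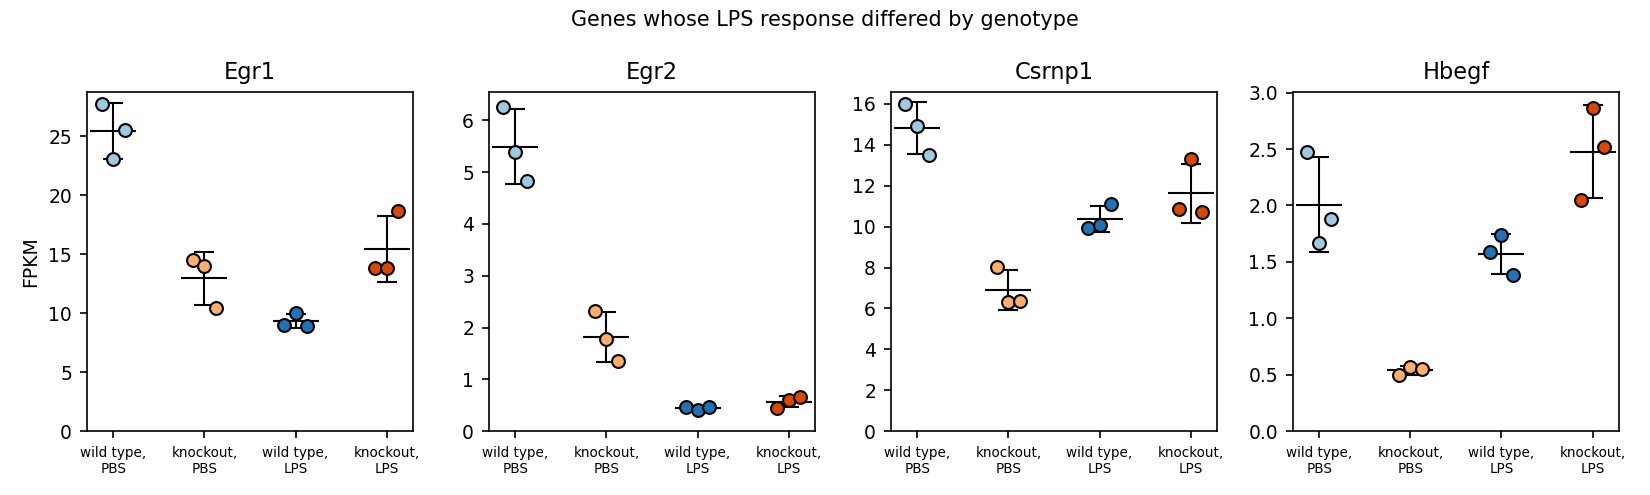
Egr1, Egr2, Csrnp1 and Hbegf in FPKM (vertical axes, from 0) in each library by genotype and treatment (horizontal axes), with group means and bars of 1 SD over 3 libraries. Each gene is lower in the knockout than in wild type under PBS, as with Egr1 at 13 and 25.5 FPKM, and not lower under LPS.

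In the mature neutrophil list the interaction had a median of 1.63, with 18 of 20 genes above 0 and 12 higher adjusted over the list alone, and 0 over all genes. S100a8 differed by 3.80 ± 0.72 (adjusted p = 0.106 by limma) and S100a9 by 3.81 ± 0.75 (adjusted p = 0.114 by limma). Il1b, which was lower with LPS in wild type and higher in the knockout, differed by 2.24 ± 0.45 (adjusted p = 0.124 by limma). Immediate early and heat shock genes had a median of 0.70, with 2 of 21 higher over all genes and 4 adjusted over the list alone, and T cell genes a median of 0.64 with 11 of 11 above 0 and 0 passing by either adjustment. Camera gave adjusted p = 1.02e-14, adjusted p = 1.56e-09 and adjusted p = 1.55e-05 for these lists, against adjusted p = 0.399 for each with an estimated correlation. An exact permutation of genotype within treatment on the mean of the neutrophil list gave p = 0.015, which became adjusted p = 0.193 over the 33 lists. The smallest value of that exact permutation, p = 0.005, was that of the Y-linked list, a check of the animals' sex. Its interaction of means was -0.217 (adjusted p = 0.165 by the permutation). Mast cell and cholesterol genes were called downward (medians -0.84 and -0.37), with camera adjusted p = 0.00248 and adjusted p = 0.00191 and, with an estimated correlation, adjusted p = 0.433 and adjusted p = 0.606. Cma1, a mast cell chymase, was at 161 ± 65.1 and 240 ± 12 FPKM in wild type and at 225 ± 49.1 and 169 ± 7.88 FPKM in the knockout under PBS and LPS (SD, n = 3). Camera called 16 lists, 14 up and 2 down, while fry and the permutation of list means called 0. Without the 2 erythroid-rich libraries camera called 13, 10 up and 3 down, with 12 of them among the 16. The monocyte, neutrophil granule, negative regulator and alternative activation calls were lost there. With 1 library left out 9 of these calls were lost in at least 1 setting. Those of monocytes, natural killer cells and glycolysis were lost without wild-type PBS replicate 2, that of cytokines without wild-type PBS replicate 1 or 2 and that of the respiratory burst without knockout LPS replicate 3. The small peritoneal macrophage and MHC class II calls were lost without wild-type PBS replicate 3 or replicate 2 of either LPS group, the latter also without knockout PBS replicate 2. The negative regulator and alternative activation calls were lost without wild-type PBS replicate 1, wild-type LPS replicate 2 or knockout LPS replicate 3. The former was also lost without replicate 2 of either PBS group and the latter without knockout LPS replicate 1. Fold changes of knockout against wild type under PBS and under LPS had Pearson r = -0.0646 and Spearman rho = -0.0485 across the 9841 genes, and with 1 library left out r ran from -0.196 to 0.0866.

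Genes called in the knockout were also compared with their distance from Ltf, since a knockout can carry chromosome of another strain around the altered gene. Within 10 Mb of Ltf, 2 of 133 tested genes were called under PBS, against 9 of the 9400 others with a position (odds ratio 15.9, two-sided Fisher exact p = 0.00978). The Fisher test takes genes as independent, which genes called from the same libraries are not. Csrnp1, at 119971163 to 119984658 on chromosome 9, was among those within 10 Mb. The call ended with a window of 5 Mb (1 of 94, odds ratio 10.1, p = 0.103), with median-of-ratios or upper-quartile scaling (odds ratio 8.89, p = 0.119 each) and without the filter (odds ratio 8.87, p = 0.119; Fisher exact tests). It also ended without wild-type PBS replicate 1 (odds ratio 1.87, p = 0.422), wild-type LPS replicate 2 or 3 (p = 0.0547 each) or knockout LPS replicate 1 or 3 (p = 0.0809 and p = 0.0937, Fisher exact tests).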

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

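Tests chosen only after the result was seen were those of blood in the lavage, the score differences between neutrophil and lymphocyte lists and the clock scores per library. The Fisher test around Ltf was planned with strain alleles in mind, but what they would predict was written down only after the result was seen.

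Mature neutrophil genes stood out because their LPS response differed between the genotypes, with a median of 1.63 in the interaction on the log2(FPKM + 1) scale, called by camera but not with an estimated correlation (adjusted p = 0.399). The values argue against 1 library as the source, since the lowest median with any of the 12 libraries left out was 1.39. They also argue against blood in the lavage as the whole source, since libraries poor in erythroid RNA differed too. Knockout LPS replicates 2 and 3, with 14.1 and 4.47 FPKM of it, held 1419 and 2956 FPKM summed over the mature neutrophil list. Wild-type LPS replicates 1 and 3, with 8.23 and 7.04 FPKM of it, held 850 and 835 FPKM. S100a8 was at 320 and 843 FPKM in the former libraries and at 51.4 and 116 FPKM in the latter. Wild-type LPS replicate 2 held 838 FPKM of the list to 2226 FPKM of erythroid RNA. At that ratio erythroid RNA would give at most 19.4% of the list sum of a knockout LPS library. The ratio rests on 1 library, where S100a8 and S100a9 made up only 103 and 80.6 of the 838 FPKM. Most of that sum came from other members, whose cells of origin were not measured, so the 19.4% need not hold for neutrophils. The erythroid median was 1.83 in the interaction. Without the 2 libraries richest in erythroid RNA it was still 1.46 beside a neutrophil median of 1.44. Wild-type PBS replicate 2, which was kept there, held 330 FPKM of erythroid RNA, against 31.0 and 31.5 FPKM in its group. The erythroid median of the knockout under PBS was -1.26. The 1.46 thus also reflects the PBS libraries and does not show whether blood added to the neutrophil difference, so a part from blood is not excluded. A lower share of macrophages in the knockout under LPS would raise every other cell type. For the difference under LPS itself the values argue against it as the whole source. B cell, T cell and natural killer medians were -0.23, -0.23 and -0.17 there, and large peritoneal macrophage genes had 0.05. The neutrophil score less the lymphocyte scores was higher by 1.65 (SE 0.469), without overlap of the libraries, by a criterion written after the values were seen. Exact permutation gave p = 0.1 for this difference, the smallest that 3 libraries against 3 can give. For the interaction such a share cannot be excluded. T cell and natural killer medians were above 0 there too (0.64 and 0.48), while B cell genes had -0.14. The score difference was 1.45 (SE 0.538, exact permutation p = 0.125) in the interaction. The neutrophil median lay 0.992 above the highest lymphocyte median, short of the difference of 1 set beforehand. An effect of genotype on neutrophil numbers or on expression in each neutrophil stays open, and cell numbers were not measured here.

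Egr1 and Egr2 of the immediate early list, and Csrnp1 and Hbegf outside it, stood out because they were lower in the knockout under PBS and their LPS responses differed by 1.59, 1.33, 1.15 and 1.39. Stress at collection cannot be told apart, since the heat shock members of the list, 3 up and 3 down, had a median of -0.0906 in the knockout under PBS, which decides nothing. Collection at another time of day cannot be told apart either: the 8 tested clock genes in antiphase to Arntl were all lower in the knockout under PBS (median -0.56, and -0.43 without wild-type PBS replicate 3, whose Dbp of 16.1 FPKM compares with 1.46 and 0.983 FPKM in its group), while Arntl was higher, but of 3 genes expected to move with Arntl 2 were lower (median -0.16; Cry1 -0.16, Nfil3 -0.30, Clock 0.21), and under LPS the antiphase median was -0.00129. The antiphase mean per library differed by -0.735 under PBS, and by -0.428 without wild-type PBS replicate 3, with an exact permutation p = 0.1 for all 6 libraries, the smallest that 3 libraries against 3 can give, so this stays a hypothesis. An effect of genotype on these genes or on the clock stays open as well, since the labels give no time of collection.

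Genes around Ltf stood out because those within 10 Mb were called in the knockout under PBS more often than others, 2 of 133 against 9 of 9400 (Fisher exact p = 0.00978). That p takes genes as independent, which genes called from the same libraries are not. A candidate explanation is alleles of another strain carried along with the knockout, which would not reach the 9 genes outside. Csrnp1, within the window, was not lower in the knockout under LPS (0.14), where a strain allele would be expected to act too. With windows of 5 Mb and 20 Mb the p was 0.103 and 0.0178 (Fisher exact tests), and the sequence of the knockout chromosome was not analysed here. A direct effect of the altered Ltf locus on genes near it stays open and was not tested.

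Besides these, camera called 15 lists in the interaction whose calls were lost with an estimated correlation, with adjusted p between 0.399 and 0.699 there. Upward medians were 0.70 for immediate early and heat shock genes, 0.64 for T cell, 0.60 for neutrophil granule, 0.55 for chemokine, 0.50 for monocyte and 0.48 for natural killer genes. MHC class II genes had 0.42, small peritoneal macrophage and dendritic cell genes 0.39, alternative activation 0.33, glycolysis 0.31, respiratory burst 0.27, cytokine and NF-kB target 0.17 and negative regulator genes 0.15. Downward medians were -0.37 for cholesterol biosynthesis and -0.84 for mast cell genes.

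For the interaction, the real grouping gave 4 genes, above the others of 100 splits of genotype within treatment, drawn from 200 possible, which gave at most 2. Such splits also break the genotype difference under PBS, where the same 4 genes were called, so they do not test the interaction alone. The real count was 0 without the 2 erythroid-rich libraries and 0 with the replicate number as a block. It was also 0 without each of 8 of the 12 libraries, so it is not a stable count, and chance is not excluded for it. Nor is chance excluded for the count of lists called by camera: 30 of the 100 splits gave at least the 16 lists of the real grouping, and the highest other gave 21. The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. There the real and the highest other counts of genes were 6123 and 0 for LPS in wild type, 5235 and 1 for LPS in the knockout, 11 and 0 for the knockout under PBS and 0 and 3 for the knockout under LPS. For lists they were 10 and 15, 8 and 17, 13 and 19, and 17 and 19.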

How the results depend on the processing

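Results without robust shrinkage, results without the 2 libraries richest in erythroid RNA and the permutation of list means were chosen only after the data were seen.

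The counts for LPS, 6123 genes in wild type and 5235 in the knockout, stayed within 1.5 times under every alternative run, as did the agreement of the LPS responses (r = 0.888 to 0.92). With each library left out in turn they were 5342 to 6138 and 4312 to 5752. Ltf stayed lower in the knockout throughout (-0.82 to -0.58 with each library left out, -1.86 with a pseudocount of 0.1). Genotype results moved. The count under PBS, 11, was 0 by limma with only the PBS groups (638 at an unadjusted p under 0.05), and 0 without the 2 erythroid-rich libraries (770). With 1 library left out it was 0 to 39: 39 without wild-type PBS replicate 1, 31 without replicate 3, 6 without replicate 2, 2, 4 and 4 without wild-type LPS replicates 1, 2 and 3, 7, 0 (480) and 0 (641) without knockout PBS replicates 1, 2 and 3, and 6, 7 and 7 without knockout LPS replicates 1, 2 and 3. The count under LPS, 0 (744 at an unadjusted p under 0.05), was 2 without the filter (Hist1h4f and Serpina3i, lower), 3 with only the LPS groups (Arg2, Cd163 and Gadd45b, higher), and 0 to 29 with 1 library left out, 29 without knockout LPS replicate 2 and 2 without wild-type PBS replicate 3. The count of the interaction, 4, was 8 with median-of-ratios scaling, 12 with upper-quartile scaling, 1 without the filter (Hist1h4f), and 0 without the 2 erythroid-rich libraries (842 at an unadjusted p under 0.05). With 1 library left out it was 0 to 49: 49 without wild-type PBS replicate 3, 36 without knockout LPS replicate 2, 11 without knockout PBS replicate 1, 3 without wild-type PBS replicate 2 and 0 without each of the others (601 to 1403). Genes of these small counts are named after their values were seen. Fewer libraries lower the power, and for the counts that grew and for the other changes the cause was not tested.

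No pairing by replicate number was seen: deviations from the group means correlated at -0.254 to 0.193 between libraries of the same number, with 5 of 18 pairs above 0.1. Between libraries of other numbers they correlated at -0.291 to 0.383, with 9 of 36 pairs above 0.1. With 3 libraries in a group a modest batch shared by number cannot be excluded. With the replicate number as a block the count under PBS was 3 (Ch25h, Csrnp1 and Egr2), the interaction 0 (899 at an unadjusted p under 0.05), the count under LPS 0 (683), and those for LPS 5991 and 5077, with an odds ratio around Ltf of 35.5 (p = 0.0413, Fisher exact).

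Camera calls were 10, 8, 13, 17 and 16 lists for LPS in wild type, LPS in the knockout, the knockout under PBS, the knockout under LPS and the interaction. With an estimated correlation they were 0 in all 5, with fry 22, 16, 0, 0 and 0, and with the permutation of list means 0 for the interaction. The calls under PBS ran from 6, without wild-type PBS replicate 1, to 16. The ribosomal protein median under PBS, -0.14, ran from -0.27 to -0.014, where without wild-type PBS replicate 3 the direction of the test turned and the call was lost. The cholesterol biosynthesis median under LPS, 0.09, ran from -0.11 to 0.27, and turned without knockout LPS replicate 1 and, at -0.076, without the 2 erythroid-rich libraries. The odds ratio around Ltf, 15.9, was 10.1 within 5 Mb (p = 0.103), 8.89 with median-of-ratios and with upper-quartile scaling (p = 0.119 each), 8.87 without the filter (p = 0.119) and 1.87 to 71.1 with 1 library left out (Fisher exact tests). It passed within 20 Mb (11.5, p = 0.0178), with the stricter filter (17.8, p = 0.00816) and with a pseudocount of 0.1 (17.9, p = 0.00808, Fisher exact tests). It did not pass without wild-type PBS replicate 1 (1.87), wild-type LPS replicates 2 or 3 (23.7 each) or knockout LPS replicates 1 or 3 (14.2 and 11.9). In each of these settings 1 called gene lay in the window instead of 2, and where no gene was called no odds ratio could be given. Of 121 named genes for LPS in wild type and 119 in the knockout, scaling ended the calls of at most 2 and 6, and no named gene reversed in any contrast. The DESeq2 Wald test and limma-voom, planned as alternatives, need counts and were not run. Reads per gene are unknown, so what depth limits cannot be stated per gene.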

Other observations

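The tests of limma, camera and fry below were planned, but the choice of Asns, Chac1, Trib3, Atf4, Idh1, Arg1, Lcn2, Slc40a1, Ngp, Gapdh and Actb, and the tests of Ltf and Ngp as singled out below, were made after the values were seen.

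Some metabolic and stress genes, named after their values were seen, moved with LPS in both genotypes. Of the unfolded protein response list, 5 of 19 genes rose and 2 fell in wild type, also adjusted over the list alone (median 0.11), and the list was not called (adjusted p = 0.125 by camera and adjusted p = 0.127 by fry). Among its members Asns, the asparagine synthetase, was at 3.12 ± 0.29, Chac1 at 3.03 ± 0.30 and Trib3 at 2.85 ± 0.28 on the log2(FPKM + 1) scale (SE), and Atf4 at 1.27 ± 0.17. In the knockout Asns rose by 2.33 ± 0.29, Chac1 by 2.76 ± 0.30 and Trib3 by 1.90 ± 0.28. Of 20 genes of the TCA cycle and fatty acid oxidation, 11 fell and 2 rose in wild type and 11 fell and 1 rose in the knockout (11 and 2, and 13 and 1, adjusted over the list alone). Camera called the list in neither (adjusted p = 0.156 and adjusted p = 0.0695), while fry called it downward in both (adjusted p = 0.00279 and adjusted p = 0.0031). The medians of the list were -0.27 and -0.28, against -0.11 and -0.12 for all tested genes. Idh1, the cytosolic isocitrate dehydrogenase, fell from 53.2 ± 36.5 to 2.85 ± 0.706 FPKM in wild type and from 41.9 ± 5.11 to 3.06 ± 1.63 FPKM in the knockout (SD, n = 3). Arg1, the arginase of alternatively activated macrophages, fell in wild type from 415 ± 197 to 68.8 ± 30.1 FPKM and in the knockout from 570 ± 119 to 81.0 ± 53.9 FPKM (SD, n = 3).

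Some iron genes and some proposed receptors of lactoferrin, named after their values were seen, responded to LPS in both genotypes, while neither list was called by camera or fry. Lcn2 rose from 183 ± 94.4 to 1496 ± 325 FPKM in wild type and from 278 ± 39.8 to 1966 ± 928 FPKM in the knockout (SD, n = 3), and Slc40a1, the iron exporter, fell by 2.31 ± 0.32 and 1.91 ± 0.32 (SE). Over 23 iron handling genes 7 rose and 9 fell in wild type, with a median of -0.44, a mean of -0.03 and no call by camera, whose direction was upward (adjusted p = 0.814). Of 6 lactoferrin receptor genes, Sdc4 and Ncl rose by 2.82 ± 0.33 and 2.21 ± 0.22 in wild type and by 2.60 ± 0.33 and 1.67 ± 0.22 in the knockout, while Cxcr4 and Lrp1 fell by 3.37 ± 0.24 and 1.88 ± 0.28 in wild type and by 2.22 ± 0.24 and 1.90 ± 0.28 in the knockout (SE). The receptor list had a median of -0.40 in wild type and 0.017 in the knockout (camera adjusted p = 0.998 and adjusted p = 0.705, and with an estimated correlation adjusted p = 0.998 and adjusted p = 0.863). Between the genotypes no gene of the list passed over all genes under PBS or LPS by limma, and adjusted over the list alone 1 was lower under PBS and 1 higher under LPS.

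Ltf in wild-type LPS replicate 2 was 1.33 FPKM, against 0.176 and 0.275 FPKM in the others of its group, and this library also had 2226 FPKM of erythroid RNA, against 8.23 and 7.04 FPKM. In a fit of all 16623 genes above 0, Ltf fell with LPS in wild type by 0.66 ± 0.22 (SE; adjusted p = 0.0318 by limma). In that fit the other differences of Ltf did not pass by limma: knockout under PBS (-0.98, adjusted p = 0.209) and under LPS (-0.48, adjusted p = 0.74), LPS in the knockout (-0.16, adjusted p = 0.634) and the interaction (0.51, adjusted p = 0.706). The precursor-stage granule gene Ngp was at 4.79 ± 3.22 FPKM in wild type and 20.4 ± 11.4 FPKM in the knockout under LPS, and at 1.99 ± 0.476 and 0.36 ± 0.253 FPKM under PBS (SD, n = 3), with an interaction of 3.03 ± 0.65 (SE) that did not pass (adjusted p = 0.181 by limma).

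Gapdh, a housekeeping gene of glycolysis, was listed at 3.18 ± 0.984 FPKM in wild type under PBS, while Actb was at 2432 ± 183 FPKM (SD, n = 3). Gapdh is 1 of the 24 glycolysis genes. How the authors assigned reads that near-identical gene copies share is not stated in the sources used here, so levels of such genes, as in the glycolysis and ribosomal protein lists, carry that limit.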
